A study of Homo sapiens with 6 samples.

How the data were processed

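Total RNA of SW-1990 cells was hybridised to 6 Affymetrix arrays, 3 from cells with a scrambled shRNA (sh-Ctrl) and 3 from cells with an shRNA against PRLR (sh-PRLR). RNA was extracted with Trizol and labelled with biotin, per the labels' protocols, which name more than 1 amplification kit without saying which was used. The deposited values are log2 expression values, 1 per probe set and array. MAS5, RMA and affy are named per the submitters' processing notes, without role or version. In the values themselves, the mean of each array on the linear scale, with 2% trimmed, was 500 on all 6 arrays, as global scaling of the MAS5 kind gives, so the deposited log2 values were taken as scaled and were not normalised again. They ran from -4.30 to 15.53, with 3211 values below 0. No background or detection call was used here, and any filter applied by the authors is not given in the sources used here.

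Of 54675 probe sets, 41091 carried 1 gene symbol in the platform annotation, 1801 carried several and 11783 carried none there. Symbols of 41037 probe sets were looked up by Entrez gene ID in a RefSeq gene table, which changed 0 of them. The 62 Affymetrix control probe sets were left out of the tests. Each gene was represented by its probe set with the highest mean over all arrays, which gave 19775 genes with a median level of 7.23. Some members of the fixed lists are not reported here, and the counts of measured members leave them out.

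The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Single probe sets of PRLR and of the other named genes were tested in a fit over all probe sets with 1 gene symbol, with adjustment over those. A 2-fold limit (log2 change of 1) gave a second count. The labels number the replicates alike in both groups but do not say that a number marks a shared culture or day, and the fit has no block. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 24 lists, with an estimated correlation and fry as alternatives. The 5 lists of cell type markers were adjusted among themselves. Single values were compared by exact permutation over the 10 splits of 6 arrays into 3 and 3, which cannot give a two-sided p under 0.1. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

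The groups, the tests, the gene lists, the markers, the rule for named genes and the first set of other settings were chosen before the data were examined. The rule names PRLR, NEK9, and up to 12 rises and 12 falls with an adjusted p under 0.05, no overlap between groups, the higher group above the median gene level and a characterised symbol. It also names up to 4 members of each list with the smallest p past an adjusted p of 0.05, and the 2 brightest members of a list that is led with and has none. It was applied to the default settings and, by a decision taken after both counts were seen, to the fit with intensity-dependent variance as well. These other settings were quantile normalisation, median centring, leaving out the 40% of genes with the lowest mean (below 5.93, leaving 11865), the mean of all probe sets of a gene, leaving out probe sets named _x_at or _s_at, eBayes with trend and robust, the replicate number as a block, each array left out, every probe set tested, and limma's treat against a fold of 1.5. A covariate for the 18S ribosomal RNA level, camera with trend after the filter on dim genes, and the alternatives to the count with intensity-dependent variance were added after seeing the data.

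The tests were checked on simulated data. Arrays were drawn for the 19775 genes with the real mean levels and with spreads of real genes of similar level, and 200 genes were changed by a log2 value of 0.5 or 1 in either direction, in 10 simulations of this comparison. With spreads as shrunk by limma in the fit with intensity-dependent variance, which favours that fit, the default settings recovered 22.8% of genes above the median level changed by 1 and 0 of those changed by 0.5, and 4.07% of the calls were false. Intensity-dependent variance recovered 96.5% and 68.0%, with 7.31% false, and the filter on dim genes, with 11865 genes, recovered 85.8% and 26.4%, with 4.68% false. With raw spreads, which vary more between genes, the recovered shares for a change of 1 were 46.4%, 79.8% and 78.1%, and the false shares 8.24%, 3.66% and 4.41%, in the same order. Below the median level at most 5.92% of genes changed by 1 were recovered by any of these fits. Camera called 2 of 480 unchanged lists and 20 of 20 lists of bright genes moved by 0.3. Simulated genes were independent, so the correlation between real genes is left out.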

Results

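Gene expression was measured in SW-1990, an established human pancreatic adenocarcinoma cell line derived from a metastasis in the spleen, on 6 Affymetrix arrays. The cells carried lentiviral short hairpin RNA (shRNA) against PRLR, the prolactin receptor, or a scrambled shRNA, and had been selected with puromycin. These groups are called sh-PRLR and sh-Ctrl. Each had 3 arrays, which the labels give as biological replicates. The comparison asks which transcripts differ after knockdown of PRLR. All values are log2, differences are sh-PRLR minus sh-Ctrl, and errors are SD over the 3 arrays of a group unless named as SE. The number of arrays limits the precision of every value.

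PRLR, the targeted gene, was measured by 7 probe sets, and the mean of each was lower in sh-PRLR. Probe set 231981_at, the brightest in sh-Ctrl, read 6.38, 6.27 and 5.77 in sh-Ctrl and 4.70, 4.83 and 5.0 in sh-PRLR, a difference of -1.30 that did not pass limma with default settings (adjusted p = 0.140 over all probe sets with 1 gene symbol). For 216638_s_at the values were 4.42, 5.12 and 4.98 against 3.56, 1.75 and 3.75, a difference of -1.82 (limma adjusted p = 0.329 over the same probe sets). The probe set with the highest mean over all arrays, 227629_at, which stands for PRLR in the gene test, read 5.75, 5.36 and 5.97 against 5.63, 5.71 and 5.05 (difference -0.23, limma adjusted p = 0.748 over the same probe sets and 0.706 over all genes). The others gave 5.50, 4.86 and 4.71 against 3.93, 4.31 and 4.48 for 206346_at, and 5.83, 4.80 and 3.06 against 1.95, 4.57 and 3.80 for 210476_s_at. For 243755_at the values were 5.37, 5.24 and 4.23 against 3.12, 5.43 and 4.78, and for 211917_s_at they were 3.38, 3.53 and 4.84 against 4.68, 4.06 and 2.46. Averaged over the 7 probe sets, PRLR was 5.02 ± 0.22 in sh-Ctrl and 4.17 ± 0.22 in sh-PRLR, a difference of -0.85 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). All 7 probe sets lay below the median gene level of 7.23, where replicates scattered widely, and which of them lie on the transcripts reached by the shRNA was not examined here.

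**Figure D1:**
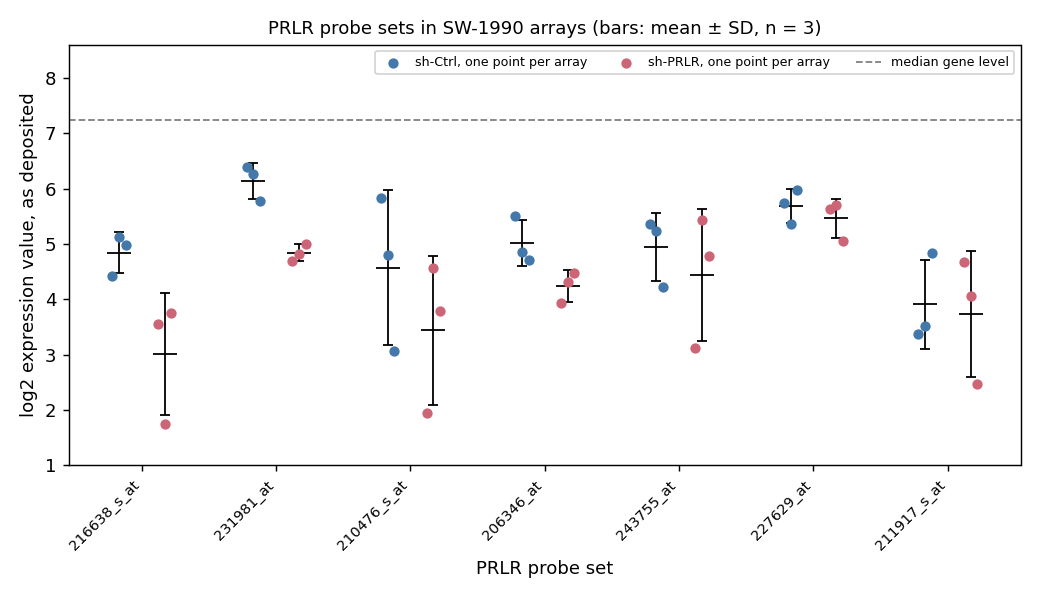
Log2 values of the 7 PRLR probe sets on each array, with sh-Ctrl in blue, sh-PRLR in red and bars for mean ± SD (n = 3). Every array of sh-PRLR lies below every array of sh-Ctrl for 216638_s_at, 231981_at and 206346_at, the arrays overlap for the other 4, and all lie below the dashed median gene level of 7.23.

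In sh-PRLR cells, the list of NRF2 target genes, part of the oxidative stress response, was higher and the list of DNA replication genes was lower than in sh-Ctrl cells by limma's camera test. The NRF2 list had an adjusted p = 0.0947 with an estimated correlation, and the DNA replication list an adjusted p = 0.0499 with an estimated correlation. AKR1C2, an aldo-keto reductase and NRF2 target, rose from 9.34 ± 0.07 to 10.64 ± 0.03, and LGR5, a receptor for R-spondins and an intestinal stem cell marker, fell from 11.36 ± 0.07 to 10.07 ± 0.02. GASK1B, which encodes a Golgi-associated protein, fell from 8.30 ± 0.02 to 6.77 ± 0.07. Of 24 gene lists fixed beforehand, 11 passed limma's camera test at its preset correlation, 7 of them higher and 4 lower, and 1, DNA replication, passed with an estimated correlation. The estimate was 0.152 for the NRF2 list but 0.000755 for the DNA replication list, below the preset 0.01. A larger p in that mode is thus not always due to correlation between members. The kinase gene NEK9, fixed beforehand for reporting, was at 11.11 ± 0.10 in sh-Ctrl and 11.16 ± 0.19 in sh-PRLR, a difference of 0.05 that did not pass (limma adjusted p = 0.879). Its dimmer probe sets 214738_s_at (0.47) and 230153_at (1.39) were higher in sh-PRLR without passing (limma adjusted p = 0.302 and 0.171 over all probe sets with 1 gene symbol).

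With limma's default settings 4 of 19775 genes passed an adjusted p of 0.05, 2 higher and 2 lower, all by at least 2-fold, while 3209 had an unadjusted p under 0.05. They were AKR1C2 (probe set 209699_x_at, log2 change 1.30, SE 0.07, adjusted p = 0.0449), LGR5 (213880_at, -1.29, SE 0.07, adjusted p = 0.0449), GASK1B (223204_at, -1.53, SE 0.07, adjusted p = 0.0396) and the uncharacterised locus LOC105376166 (2.47, SE 0.11, adjusted p = 0.0396). The last was named after its values were seen, as it lies at a low level, 3.26 ± 0.15 against 5.73 ± 0.08, and outside the rule for named genes. With the variance allowed to depend on intensity (limma trend and robust), an alternative fixed before the data were examined, 1514 genes passed, 660 higher and 854 lower, and 97 of them changed by at least 2-fold. Without the 40% of genes at the lowest level, the default settings called 1144 of 11865 genes, 446 higher and 698 lower. The 2 alternatives shared 972 called genes, whose direction could not differ, as both use the same log2 changes. Centring each array on its median left 504 genes with intensity-dependent variance, 143 higher and 361 lower, so that 28.4% were higher in place of 43.6%. Of all genes tested, 25.8% had every array of one group above every array of the other, against 10% by chance. To use the intensity-dependent test for naming genes below was decided after both counts were seen, and "rose" and "fell" refer to it from here on.

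**Figure D2:**
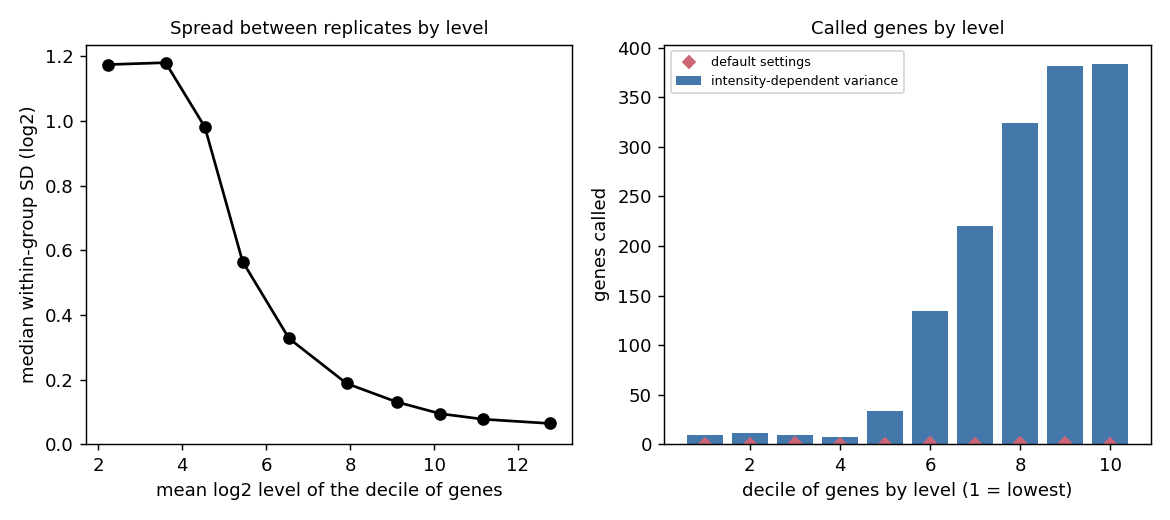
Left, the median within-group SD (log2) of each decile of genes by level against its mean log2 level, with SDs from 1.17 in the lowest decile to 0.064 in the highest. Right, the number of genes called in each decile, as bars with intensity-dependent variance (384 in the highest decile) and as diamonds with default settings (at most 1 in any decile).

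Among genes whose higher group lay above the median gene level, the 12 largest rises were led by the forkhead factor FOXL1 (1.72), NLRC5, an activator of MHC class I genes (1.47), DUSP5, a phosphatase of ERK (1.38), and MYLK, the myosin light chain kinase (1.35). They also held AKR1C2, the mucin-type glycosyltransferase GCNT3 (1.29), HMOX1, heme oxygenase (1.25), CYP4F3, a leukotriene hydroxylase (1.24), and the antisense transcript HSD11B1-AS1 (1.23). AKR1C1 (1.18), CXCL8, the chemokine interleukin-8 (1.16), and the acyl-CoA synthetase ACSL5 (1.11) completed the 12. DUSP5 was the brightest of them, at 11.51 ± 0.05 in sh-Ctrl and 12.90 ± 0.14 in sh-PRLR. AKR1C1 and AKR1C2 are close paralogs read by probe sets that can cross-hybridise, so the share of each is uncertain. HSD11B1-AS1 was read by 1 probe set, and whether its signal is separate from that of its sense partner was not tested.

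By the same limit on the higher group, the 12 largest falls were led by PTGIR, the prostacyclin receptor, at 7.50 ± 0.48 in sh-Ctrl and 4.92 ± 0.33 in sh-PRLR (-2.58), and by the chromatin protein ARID5B (-1.80). HSD3B1, a steroid-synthesising enzyme (-1.62), LRATD1 (-1.58), GASK1B, the calcium sensor VSNL1 (-1.41) and NDP, a ligand of a Wnt receptor (-1.41), followed. IGFBP7 (-1.36), the vesicle trafficking gene SYTL2 (-1.32), the receptor FGFR3 (-1.32), the chloride channel CFTR (-1.31) and CEP128 (-1.31) completed them. The fall of PTGIR rests on 1 of its 2 probe sets, as the other was at 5.70 in sh-Ctrl and 5.61 in sh-PRLR (-0.08) and did not pass. The sh-PRLR mean of 4.92 lay below the limit of 5.93 used for dim genes, so the size of that fall is uncertain. The sh-PRLR mean of HSD3B1, 5.92, also lay just below that limit. For FOXL1, HSD3B1 and FGFR3, 1 of 2 probe sets had the sign given here, and the other went the opposite way without passing. Probe sets of the opposite sign, without passing, were also present for AKR1C1 (3 of 5 had the sign given), ARID5B (3 of 5), CFTR (4 of 6), LRATD1 (5 of 7), MYLK (4 of 5) and CEP128 (4 of 5). HSD3B1 was higher in sh-PRLR by 0.76, without passing, when its 2 probe sets were averaged.

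**Figure D3:**
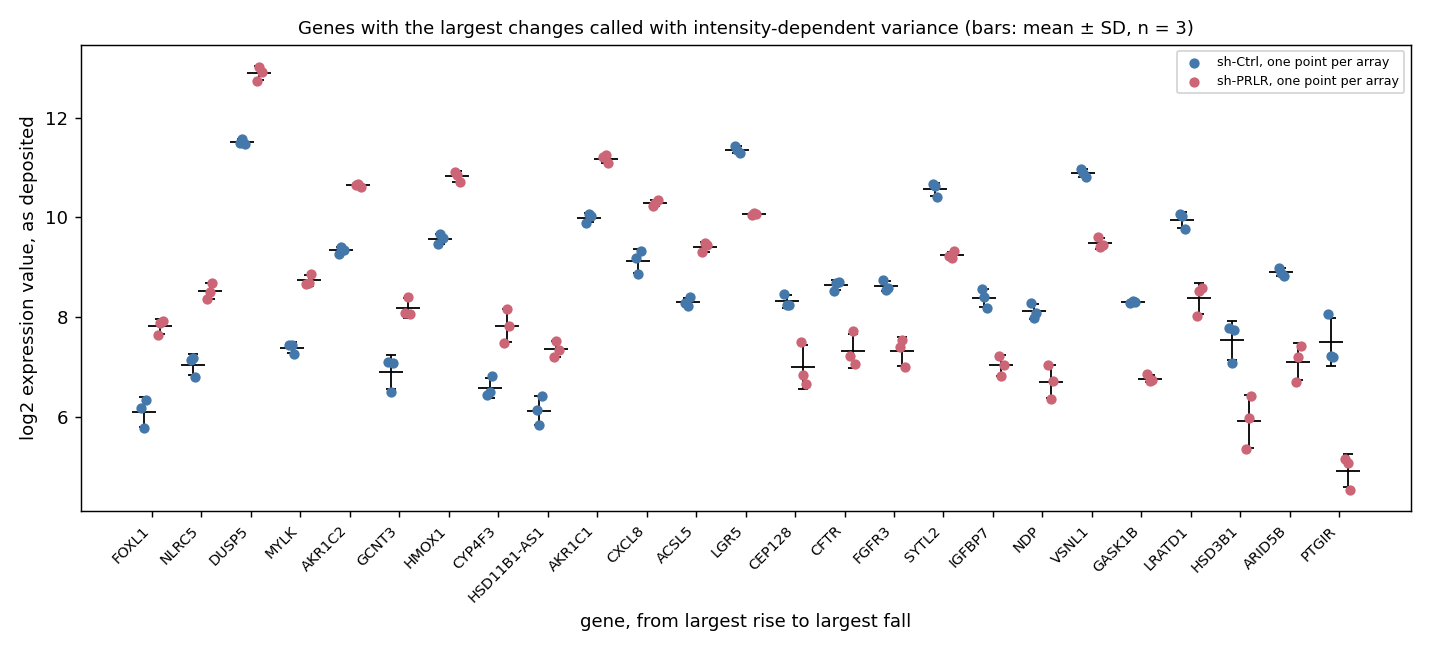
Log2 values on each array of the genes with the largest changes called with intensity-dependent variance, and of LGR5, ordered from FOXL1 (1.72) to PTGIR (-2.58), with sh-Ctrl in blue, sh-PRLR in red and bars for mean ± SD (n = 3). The arrays of the groups do not overlap for any gene shown, which the rule for named genes required.

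NRF2 target genes, which encode antioxidant and detoxifying enzymes, had the smallest p of the lists that were higher. All 12 members were higher in sh-PRLR, with a median log2 change of 0.60, and 11 rose, 11 also when adjusted over the list alone. With default settings 1 passed over all genes, AKR1C2, and 10 passed adjusted over the list alone. Besides AKR1C2, AKR1C1 and HMOX1, GCLM, a subunit of the enzyme that starts glutathione synthesis, rose from 12.86 ± 0.04 to 13.52 ± 0.05. The list passed limma's camera with an adjusted p = 5.31e-13, and had an adjusted p = 0.0947 with an estimated correlation.

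DNA replication and G1/S genes were lower in 21 of 22 cases, with a median of -0.35. Of these 11 fell, 15 adjusted over the list alone, against 0 over all genes and 10 adjusted over the list alone with default settings. UHRF1, a reader of hemimethylated DNA, fell from 11.81 ± 0.11 to 10.93 ± 0.03, and MCM3, part of the replicative helicase, fell from 12.37 ± 0.04 to 11.79 ± 0.01. GINS2, another helicase component (-0.91), and cyclin E gene CCNE2 (-0.75) fell as well. This list passed camera (limma adjusted p = 9.53e-10, and adjusted p = 0.0499 with an estimated correlation) and was the 1 list of 24 that passed with an estimated correlation. Mitosis and G2/M genes had a median of 0.01, and 2 of 20 rose, UBE2C (0.25) and AURKA (0.26), with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.813). Nucleotide synthesis genes had a median of -0.17, and 4 of 20 fell, among them TYMS, thymidylate synthase (-0.26), and CTPS1, CTP synthase (-0.47), with 10 lower and 1 higher adjusted over the list alone. That list passed camera at adjusted p = 0.0221, and had an adjusted p = 0.282 with an estimated correlation, and the call was lost in 6 of 16 alternatives, the others being the filter on dim genes, the replicate block, leaving out _x_at and _s_at probe sets, and leaving out sh-Ctrl replicate 3 or sh-PRLR replicate 3.

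The p53 target genes passed camera toward lower values (adjusted p = 0.00119, and adjusted p = 0.104 with an estimated correlation). Their median was -0.24, and 6 of 17 fell and 2 rose, with 10 lower and 2 higher adjusted over the list alone. ZMAT3 (-0.60) and MDM2, the ubiquitin ligase of p53 (-0.42), fell, whereas the death receptor gene TNFRSF10B (0.49) and the stress cytokine GDF15 (0.40), both also induced by other stress pathways, rose. Interferon-stimulated genes passed camera toward lower values as well (adjusted p = 0.00358, and adjusted p = 0.126 with an estimated correlation). Their median was -0.41, 17 of 21 were lower, and 2 fell, also 2 adjusted over the list alone: IFI6, from 9.24 ± 0.07 to 8.17 ± 0.08, and ISG15 (-0.29). In this list 12 of 21 members lay below the median gene level.

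Several stress and signalling lists were higher in sh-PRLR. Of 15 ERK output genes 5 rose and 1 fell, 9 and 1 adjusted over the list alone, with DUSP5, FOSL1 (0.95), the receptor EPHA2 (0.38) and the phosphatase DUSP6 (0.29) among the rises. Camera gave an adjusted p = 0.00162, and an adjusted p = 0.104 with an estimated correlation. Of 18 NF-kB and inflammatory genes 3 rose, CXCL8, IER3 (0.62) and CXCL2 (0.73), and PTGS2, cyclooxygenase-2, fell (-0.52), with 5 higher and 1 lower adjusted over the list alone. Camera gave an adjusted p = 0.00119, and an adjusted p = 0.132 with an estimated correlation. Of 14 lysosome and autophagy genes 6 rose and 1 fell, 7 and 1 adjusted over the list alone, with the protease gene CTSL (0.77), the autophagy receptor SQSTM1 (0.53), WIPI1 (0.58) and the cholesterol exporter NPC1 (0.40) among the rises. That list had an adjusted p = 0.00175 by camera, and an adjusted p = 0.104 with an estimated correlation. NPC1 was lower by -0.27, without passing, when its probe sets were averaged.

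Of 18 hypoxia-induced genes 7 rose and 1 fell, 8 and 3 adjusted over the list alone. NDRG1 rose from 10.10 ± 0.10 to 10.99 ± 0.07, and SLC2A3, a glucose transporter (0.72), VEGFA (0.41) and DDIT4, an inhibitor of mTORC1 (0.36), rose too. The list had an adjusted p = 0.0115 by camera, and an adjusted p = 0.126 with an estimated correlation. Without sh-PRLR replicate 2 this list no longer passed. Of 15 unfolded protein response genes 6 rose, 9 adjusted over the list alone, including the chaperone genes DNAJB9 (0.42) and HSPA5 (0.23), EDEM1 (0.34) and the transcription factor XBP1 (0.30), with an adjusted p = 0.00259 by camera and an adjusted p = 0.327 with an estimated correlation. Of 19 genes of prolactin receptor and STAT5 signalling 3 rose, the adaptor SHC1 (0.55), the kinase PIM1 (0.46) and cyclin D gene CCND1 (0.25), 4 adjusted over the list alone. It had an adjusted p = 0.0448 by camera, and an adjusted p = 0.282 with an estimated correlation, and the call was lost in 11 of 16 alternatives, among them median centring and leaving out replicate 2 or 3 of either group.

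**Figure D4:**
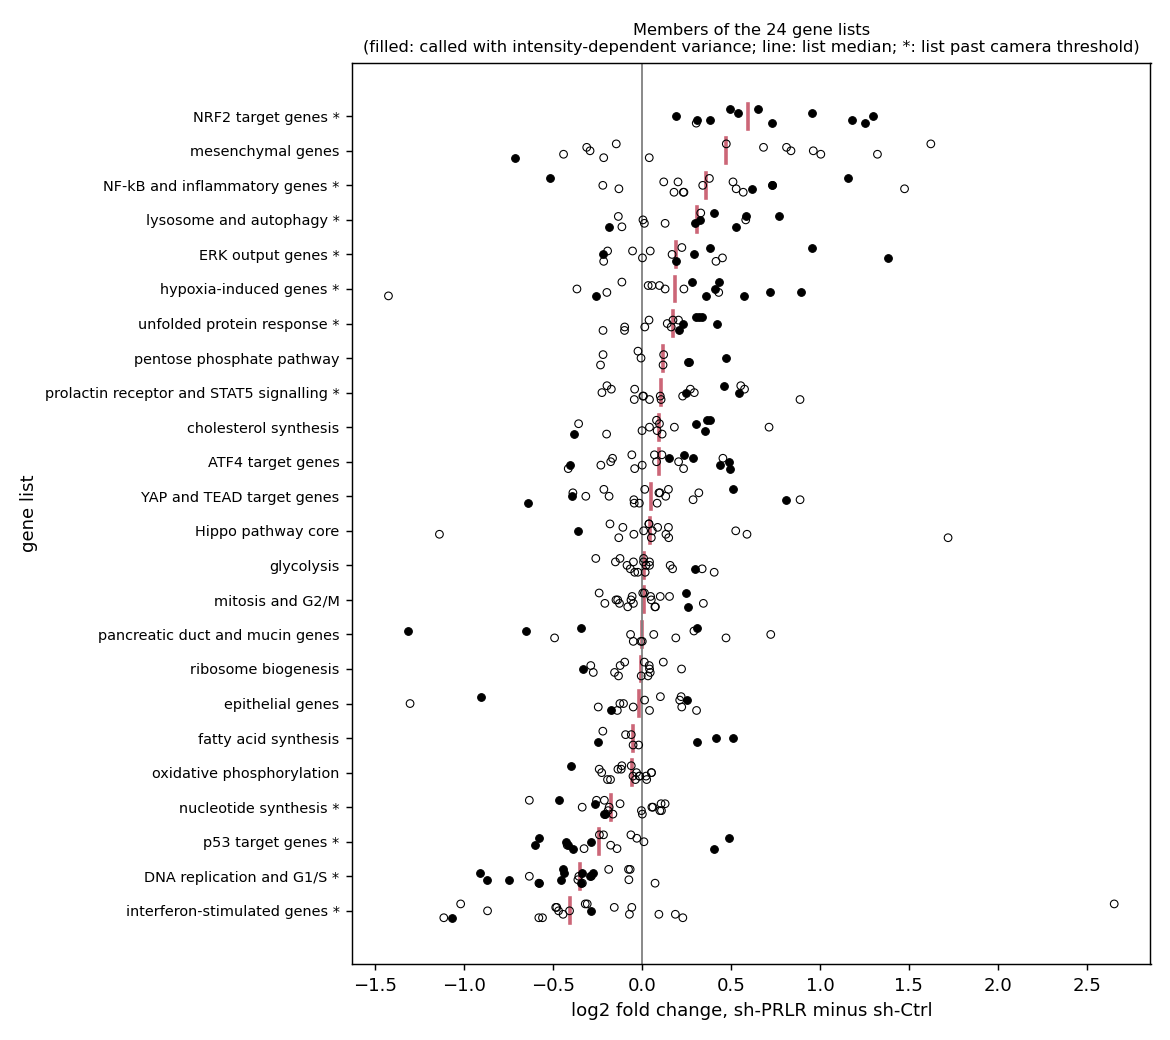
Log2 change of each measured member of the 24 gene lists, sh-PRLR minus sh-Ctrl, with filled points for members called with intensity-dependent variance, a red line for the list median and an asterisk for the 11 lists past limma's camera. The medians run from -0.41 for interferon-stimulated genes to 0.60 for NRF2 target genes.

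The other 13 lists did not pass camera with default settings. With intensity-dependent variance camera also passed ATF4 target genes (limma adjusted p = 0.0293), cholesterol synthesis (0.0293) and oxidative phosphorylation (0.0164), and fry passed ATF4 target genes (limma adjusted p = 0.0470), cholesterol synthesis (0.0161) and the pentose phosphate pathway. In the pentose phosphate pathway, TKT (0.47), TALDO1 (0.26) and PGD (0.27) rose, 3 of 9 members, with 3 higher and 1 lower adjusted over the list alone (limma camera adjusted p = 0.331, and limma fry adjusted p = 0.0105). Glycolysis had a median of 0.01, and 1 of 19 members rose, PKM (0.30), with 0 adjusted over the list alone (limma camera adjusted p = 0.653). Among 20 YAP and TEAD target genes, F3 (0.51) and NT5E (0.81) rose and PTPN14 (-0.39) and FJX1 (-0.64) fell, the same numbers adjusted over the list alone (limma camera adjusted p = 0.608). Among 18 genes of the Hippo pathway core, SAV1 fell (-0.36), also 1 adjusted over the list alone (limma camera adjusted p = 0.350). Of 20 ATF4 target genes 6 rose, including SLC7A11 (0.50), DDIT3 (0.44) and TRIB3 (0.29), and 1 fell, SLC7A5 (-0.40), with 9 and 4 adjusted over the list alone (limma camera adjusted p = 0.102).

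Of 15 measured cholesterol synthesis genes 4 rose, including INSIG1 (0.38), STARD4 (0.37) and IDI1 (0.30), and LSS fell (-0.38), with 4 and 2 adjusted over the list alone (limma camera adjusted p = 0.112). In fatty acid synthesis SCD (0.42), ME1 (0.31) and ACSS2 (0.51) rose and ACLY fell (-0.25), the same numbers adjusted over the list alone. The median of those 9 members was -0.05 while their mean was 0.06 and camera pointed upward (limma adjusted p = 0.514). Oxidative phosphorylation had a median of -0.06, with NDUFA9 falling (-0.40), 1 of 18 and 2 adjusted over the list alone (limma camera adjusted p = 0.0542). In ribosome biogenesis RRS1 fell (-0.33), 1 of 15 and 2 adjusted over the list alone (limma camera adjusted p = 0.331).

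Of 16 epithelial genes ELF3 (-0.90) and CDH1, E-cadherin (-0.17), fell and OCLN, occludin (0.25), rose, with 3 lower and 3 higher adjusted over the list alone (limma camera adjusted p = 0.896). Of 15 mesenchymal genes THBS1 fell (-0.71), also 1 adjusted over the list alone, and 13 lay below the median gene level (limma camera adjusted p = 0.375). THBS1 was higher by 0.49, without passing, when _x_at and _s_at probe sets were left out. Of 14 pancreatic duct and mucin genes CFTR, GATA6 (-0.34) and the trefoil factor TFF3 (-0.65) fell and S100P (0.31) rose, with 3 lower and 2 higher adjusted over the list alone (limma camera adjusted p = 0.608). Of the markers of other cell types, 0 of 30 measured passed the default or the intensity-dependent test, and 0 of 5 marker lists passed camera. Adjusted over the list alone, 1 of 7 fibroblast markers, PDGFRA (-2.03, named after its values were seen), was lower with default settings and 0 with intensity-dependent variance, and 0 markers of the other 4 lists passed either way. The adjusted p from limma's camera was 0.432 for acinar, 0.379 for endocrine, 0.371 for fibroblast, 0.998 for leukocyte and 0.371 for endothelial markers. By fry the acinar and fibroblast markers were lower (limma adjusted p = 0.0238 for both), at mean levels of 3.80 and 4.83. The brightest markers were COL1A1 at 7.79 ± 0.15 and 7.99 ± 0.16, CD74 at 7.59 ± 0.11 and 7.45 ± 0.25, and PECAM1 at 7.08 ± 0.20 and 7.46 ± 0.27 in sh-Ctrl and sh-PRLR.

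Array medians were 5.93 ± 0.07 in sh-Ctrl and 5.96 ± 0.11 in sh-PRLR (exact permutation p = 0.6, in a test that cannot go below 0.1), and ranged from 5.86 to 6.07 over the 6 arrays. The 18S ribosomal RNA control probe sets read 12.99 ± 0.34 in sh-Ctrl and 13.48 ± 0.18 in sh-PRLR (exact permutation p = 0.3), with sh-Ctrl replicate 3 at 13.39 among the sh-PRLR arrays, and the 1514 genes became 385 with this level as a covariate, an alternative chosen after seeing the data. The 3′ minus 5′ difference of the ACTB controls was 3.22 ± 0.16 against 3.04 ± 0.06 and that of the GAPDH controls 0.22 ± 0.05 against 0.13 ± 0.06 (exact permutation p = 0.2 for each). The 4 genes called with default settings became 0 when any 1 array was left out, and the 1514 became 821, 665 and 893 without sh-Ctrl replicate 1, 2 and 3, 859 without sh-PRLR replicate 2 and 948 without sh-PRLR replicate 3. Averaging probe sets per gene gave 0 genes with default settings and 609 with intensity-dependent variance. Without _x_at and _s_at probe sets 4 lists passed in place of 11: DNA replication, interferon-stimulated, NRF2 target and ERK output genes. That setting also removes genes outright, leaving 74 of 94 genes followed across settings, and reads others by another probe set. Whether cross-hybridisation accounts for the lost calls thus cannot be told from it.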

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

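The tests of the fold changes with the 18S level as a covariate, of the NRF2 list without paralogs, of the mitosis list and of other splits of the arrays for the gene counts were chosen only after the result was seen.

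Of 11721 probe sets without a gene name here, which no comparison used, 11 were higher in sh-PRLR on every array and passed limma's intensity-dependent test, 10 were lower, and 0 passed with default settings. The 18S ribosomal RNA control probe sets, also outside the comparisons, were higher in sh-PRLR by 0.49 on average, although sh-Ctrl replicate 3 (13.39) lay above 2 of the 3 sh-PRLR arrays, by the most over replicate 2 (13.37).

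The first pattern is that 4 genes passed with default settings and 1514 with intensity-dependent variance. In simulated arrays with a spread that falls with level, the default settings recovered 22.8% of genes above the median level changed by a log2 value of 1. Intensity-dependent variance recovered 96.5% of them (46.4% against 79.8% with raw spreads), and the filter on dim genes gave 1144 calls on the real arrays. A spread that depends on level can thus lower the default count. With 200 changed genes, the simulations gave on average 11.9 calls with default settings and 89.6 with intensity-dependent variance (25.3 against 63.3 with raw spreads). They thus did not reproduce a gap as wide as 4 against 1514. In the default fit the spread shared by all genes was an SD of 0.164, with a weight of 1.00 degrees of freedom. With intensity-dependent variance the median weight was 6.47. Whether the shared spread or its small weight lowered the count was not tested. Carry-over of ribosomal RNA predicts that sh-Ctrl replicate 3 should approach sh-PRLR, as its 18S level does (86.6% of the way). Yet over the 893 genes called without it the median position was 8.36% (bootstrap over genes, 6.47 to 10.4). This value, from 1 array, argues against carry-over as the whole cause for those genes. With the 18S level as a covariate the 1514 genes kept a median of 99.4% of their log2 change, all with the same sign. These genes were called on the same arrays, which favours small scatter within groups, and the 18S slope is estimated from that scatter. High retention was thus favoured beforehand, and no conclusion is drawn from it. The covariate widened the standard errors 1.48-fold, used a degree of freedom and left 385 calls. The 10 splits of the arrays are too few for a share under 0.05: 1 split, the real one, gave as many genes, with 4 against at most 2 elsewhere for default settings, also with the 2-fold limit, 1514 against 0 with intensity-dependent variance, and 11 lists against 2, and knockdown of PRLR and other effects of this shRNA stay open, as untested.

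The second pattern is the rise of NRF2 target genes. Cross-hybridisation among aldo-keto reductases predicts that the rise ends without them, yet without AKR1C1, AKR1C2 and AKR1B10 the other 9 members had a median of 0.54, ranging from 0.19 to 1.25 (limma camera p = 3.47e-11, and p = 0.00610 with an estimated correlation). A rise shared by all bright genes is also argued against: the list median of 0.60 lay at percentile 100 of 10000 random lists matched on level, whose highest median was 0.26. A response of the cells to lower PRLR is a hypothesis for this pattern, and an off-target effect of the shRNA, for which these arrays hold no other shRNA, may give the same values.

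The third pattern is that 11 of 22 DNA replication genes fell and 0 rose, while 2 of 20 mitosis genes rose and 0 fell. A smaller share of cycling cells alone would lower both, yet the mitosis list differed by 0.0135 on average. Its 9 differences between single arrays ran from -0.03 to 0.08. The DNA replication list differed by -0.39, from -0.44 to -0.33. The difference between the lists was -0.40, and exchanging members between them gave a permutation p = 1e-05, the smallest that 100000 resamples can give. Genes are not independent, and the replication list was picked for its fall, so a small p was favoured beforehand. Lower expression of replication genes within cycling cells may give these values. More cells past S phase would be expected to raise the mitosis list, which did not rise as a list, although 2 of 20 members did. Neither was tested.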

How the results depend on the processing

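The variants of the count with intensity-dependent variance, the 18S covariate, and camera with trend after the filter on dim genes were chosen after seeing the data. The default count of 4 genes became 24 after quantile normalisation, 1144 with the filter on dim genes and 1514 with intensity-dependent variance. It became 0 after median centring, with the mean of all probe sets, without _x_at and _s_at probe sets, with every probe set tested, with the replicate block, with the 18S covariate, and without any 1 array (lowest 0, highest 0). The 4 genes changed at least 2-fold became 16, 54 and 97 under the first 3 of these, and 0 after median centring, with the mean of all probe sets, without _x_at and _s_at probe sets, with the replicate block, with treat against a fold of 1.5, and without any 1 array (lowest 0, highest 0). The 1514 genes became 504 after median centring (502 of them among the 1514), 609 with the mean of all probe sets, 385 with the 18S covariate and 665 to 1322 without 1 array. They stayed within 1.5 times after quantile normalisation (1548), with the filter on dim genes (2026), without _x_at and _s_at probe sets (1011), with every probe set tested (1918) and with the replicate block (1090). The 11 lists became 4 without _x_at and _s_at probe sets and 1 with an estimated correlation, and 9 to 14 elsewhere, 9 to 12 of them without 1 array. DNA replication passed in 16 of 16 alternatives (adjusted p from 1.20e-13 to 0.0499), ERK output, interferon-stimulated and NRF2 target genes in 15, and 0 of the 11 lists turned direction. PRLR stayed below 0 and short of the threshold throughout, from -0.02 to -0.85, with no value under the filter on dim genes, which leaves it out.

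Of 94 genes followed, 5 values turned sign: HSD3B1 (0.76) and NPC1 (-0.27) with the mean of all probe sets, THBS1 (0.49) without _x_at and _s_at probe sets, and NEK9 without sh-Ctrl replicate 1 (-0.0073) and without sh-PRLR replicate 1 (-0.046), in a range up to 0.146 without 1 array. Except for the filters and left-out arrays, which change the genes or arrays in the fit, the cause was not tested. The replicate numbers share no deviations (same-number correlations -0.07, 0.04 and -0.10, and not every array correlated best with its own number), so the block removes degrees of freedom, and 9 lists passed with it. Median gene change was -0.00135 as deposited. It was 0.0453 with the tested genes centred on their own array medians, which is not the median centring above. That setting used the medians of all probe sets, which were higher in sh-PRLR by 0.0336, and so lowered every gene change. Alternatives for the pseudocount were not run, as the values are already log2. Signal limits what can be seen: SD was 1.17 in the lowest decile of genes by level and 0.064 in the highest, and 70 of the 1514 genes lay below the median level.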

Other observations

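Both tests here were chosen after the main results were seen. Genes were grouped by the stem of their symbol into 109 families with at least 12 members above the lowest 40% by level. None passed limma's camera with trend after adjustment over the families. The smallest p belonged to the KLF transcription factors (13 members, median 0.16, 5 rising and 0 falling with intensity-dependent variance, p = 0.00211, adjusted p = 0.117, unadjusted p = 0.0402 with an estimated correlation). Tetraspanins (TSPAN, 18 members) had a median of -0.15, with 5 falling and 0 rising (limma camera adjusted p = 0.389).

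LGR5 and APCDD1, both known targets of Wnt signalling, were lower in sh-PRLR, APCDD1 by -1.09 (limma adjusted p = 0.0713 with default settings and 0.00900 with intensity-dependent variance), and APCDD1 is named here after its values were seen. The hypothesis that Wnt target genes fell together was tested on 15 measured members of a list written before its test, with LGR5 and APCDD1 left out. The median was -0.33, 11 of 15 were lower, and 4 fell and 0 rose with intensity-dependent variance (limma camera p = 0.000892, and p = 0.0238 with an estimated correlation). CCND1 and MYC, often counted as Wnt targets too, were not in that list. CCND1 rose by 0.25, and MYC was at -0.04 and did not pass, so the result holds for the listed members. AXIN2, a feedback inhibitor of the pathway (-0.44), ZNRF3, another (-0.42), BMP4 (-0.42) and CD44 (-0.40) fell, while RNF43 was at 0.25 and did not pass. Lower Wnt target expression in sh-PRLR may give the values of the list, as a hypothesis found and tested on the same arrays. An off-target effect of the shRNA stays open.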
